A study of Homo sapiens with 12 samples.

How the data were processed

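Sections of postmortem human anterior hippocampus from 10 neurotypical donors were measured with Visium, which captures RNA on an array of 4992 barcoded spots per capture area. Sections of 2 of these donors (donors 3 and 8) were measured again with Visium-SPG, in which the section is also stained with antibodies. The 12 samples held 42 capture areas, 34 of Visium and 8 of Visium-SPG, and a donor's areas were summed. Samples are named by group and donor, and the donors of the Visium-SPG samples were taken from the sample titles, which repeat those of Visium donors 3 and 8.

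The deposited matrices hold UMI counts, that is counts of distinct captured RNA molecules, for 36601 genes in each spot, per the file headers. The headers name Cell Ranger 4 in the 34 Visium areas and Space Ranger 2.0.0 in the 8 Visium-SPG areas. The submitters' processing notes name Space Ranger and the genome build GRCh38, so the 2 sources differ for the Visium areas. No normalised values were used, and every value below was computed from the counts. A further pair of matrices listed under a Visium-SPG sample was identical byte for byte to matrices of Visium donor 2 and was not used. Further capture areas of Visium donor 2 that the study lists were not analysed here. Images, image scale factors, the sample tables and the single-nucleus experiment were not used here.

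Spots over tissue with at least 300 UMIs and at least 200 genes were kept, which left 179681 of 183039 spots over tissue (141729 Visium and 37952 Visium-SPG) and removed 3358. No doublet caller was applied, since a spot covers several cells. XIST and the Y-linked genes, 90 features together, were left out of all tables. Kept UMIs came to 16994262 to 66663392 per Visium donor, and to 101929990 and 105186966 in the Visium-SPG samples. Intervals and limits for counts of 0 cover counting error only. They are 95% Wilson intervals and the limit that 3 counts would set.

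Regions were defined with a panel of 60 genes in 9 marker lists, fixed before the data were examined. Each spot's log2(1 + UMIs per 10000) was averaged with its up to 6 grid neighbours, scaled to z values over the Visium spots (limited to 5 either way), weighted by list size and clustered by k-means with 20 clusters and a fixed seed of 7. A cluster took the list with the highest mean z if this exceeded 0.2 and at least 3 markers had a positive mean. Visium-SPG spots went to the nearest Visium centre. Of 20 clusters, 19 were placed and cluster 8 stayed unnamed. The regions are called by a pair of leading genes throughout, and some genes are not reported here. They are CALB1/PPFIA2 (granule cell list, clusters 3 and 15), NEUROD6/FIBCD1 (pyramidal cell list, clusters 4, 10, 14 and 18), TESPA1/RXFP1 (cortical neuron list, clusters 7 and 20), GAD1/SLC32A1 (GABAergic neuron list, clusters 5, 6 and 19), AQP4/SLC1A2 (neuropil list, clusters 9 and 13), MBP/MOBP (white matter list, clusters 2, 16 and 17), TTR/FOLR1 (choroid plexus list, cluster 12), CFAP126/PIFO (ependymal list, cluster 11) and TAGLN/ACTA2 (vascular list, cluster 1). Each cluster's 10 genes of highest fold over the other clusters were checked against the lists. In cluster 17 they held 1 marker of the GABAergic list and none of the white matter list, and in clusters 9, 13 and 15 none of any list. Clusters 9 and 15 stayed in every count. The count of calls without clusters 13 and 17 was therefore added after the data were examined.

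Counts were summed per donor and region, so the donor was the replicate and the tests were paired within donors. A donor entered a comparison with at least 30 spots on each side. The pairing comes from the tissue itself, since both sides of a comparison are the same donor. Genes passing edgeR's filterByExpr were fitted with edgeR's quasi-likelihood model (TMM scaling, donor as a block). A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 fold change of at least 1. The panel genes were not tested between regions. Standard errors are the log2 fold change divided by the square root of its F statistic. Values in CPM (counts scaled to the library total) are means ± SD over donors. The fit was tested on simulated data with 200 changed genes per comparison, 100 at a log2 fold of 1.5 and 100 at 3.0. Of the genes changed by 1.5, it recovered from 81% (TAGLN/ACTA2 against other spots, 15409 genes fitted) to 97% (MBP/MOBP against AQP4/SLC1A2, 13608 genes fitted).

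Named genes follow a rule fixed before the data were examined. Among called genes with a mean log2 CPM of at least 5 and the same direction in every donor compared, these are the 12 with the largest change each way, without clone-based symbols and mitochondrial-encoded genes, and members of 25 gene lists. The lists cover mitochondrial-encoded genes, nuclear oxidative phosphorylation genes, ribosomal proteins, presynaptic and postsynaptic genes, general neuronal genes, GABA-A receptor subunits, potassium channels, neuromodulator receptors, neuropeptides, further interneuron genes, immediate early genes, heat shock genes, glucocorticoid response genes and genes of immature or cycling cells. The others hold further genes of oligodendrocytes, their precursors, astrocytes, microglia, lymphocytes, blood, endothelial and mural cells, fibroblasts, choroid plexus and cilia. Lists with at least 4 tested members were tested against all other genes with limma's camera, with a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison.

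The planned comparisons in the Visium donors were CALB1/PPFIA2 against NEUROD6/FIBCD1, NEUROD6/FIBCD1 against TESPA1/RXFP1 and against AQP4/SLC1A2, MBP/MOBP against AQP4/SLC1A2, and the TTR/FOLR1, TAGLN/ACTA2 and GAD1/SLC32A1 regions each against all other spots. Visium-SPG was compared with Visium in donors 3 and 8 over all spots, in the MBP/MOBP region and in the AQP4/SLC1A2 region. CFAP126/PIFO against other spots, clusters 4 and 10 against 14 and 18, and the difference of a region contrast between the assays were added after the data were examined. Alternatives were DESeq2 size factors, the DESeq2 Wald test, no filter on low counts, no donor block, regions without averaging over neighbours, with 12 or 30 clusters or by direct assignment, at least 1000 UMIs per spot, at least 100 spots per donor and region, no mitochondrial-encoded genes, Visium-SPG spots added, only spots whose leading score led by 0.5, no fold threshold and leaving out each donor in turn. To test chance, region labels were swapped within donors in up to 41 arrangements, the real one included. The regions were drawn from the counts of the same spots, so p values between regions describe the regions as drawn and do not test whether they exist.

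Positions and genomic spans come from a RefSeq gene table of GRCh38.p14, matched by symbol, which gave a span for 23793 of the 36601 features and a position for all 211 genes of the rule. Software was Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.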

Results

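RNA was counted spot by spot in sections of human anterior hippocampus from 10 donors by Visium, and in further sections of donors 3 and 8 by Visium-SPG. Visium donors 1 to 10 gave 42328277, 16994262, 66537155, 66663392, 21279350, 31668172, 44158255, 55798220, 20328671 and 40124488 UMIs in kept spots. Visium-SPG donors 3 and 8 gave 101929990 and 105186966. The median kept spot held 1646 to 3675.5 UMIs in the Visium donors, and 4214 and 3869 in the Visium-SPG samples. Mitochondrial-encoded genes took 9.45% to 20.3% of a sample's UMIs.

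**Figure D1:**
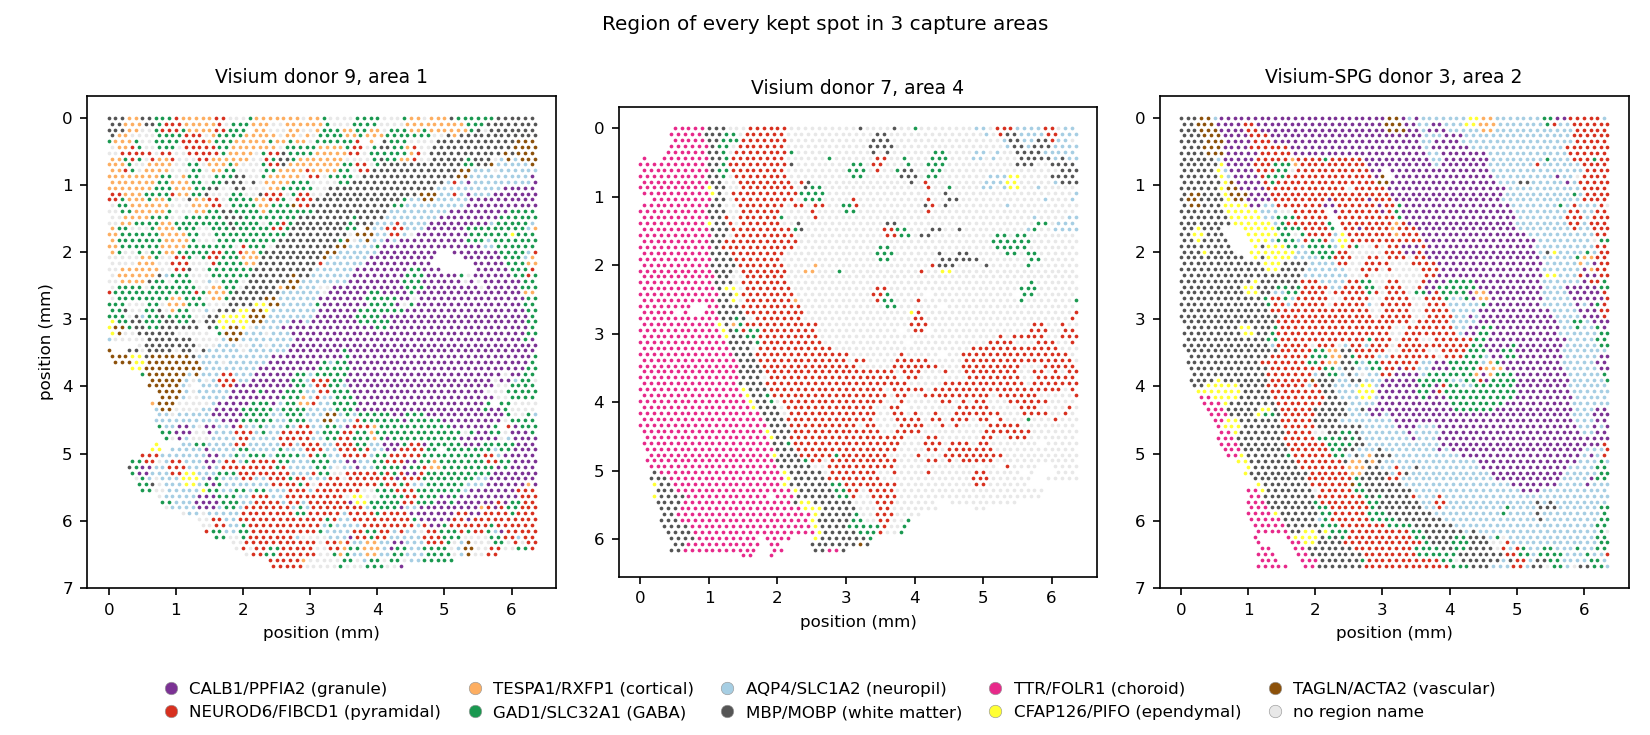
Each dot is a kept spot at its place in 1 capture area (axes in mm), coloured by the region its cluster was given, for 3 areas chosen by their number of CALB1/PPFIA2 or TTR/FOLR1 spots. The CALB1/PPFIA2 region held 1081 spots in the area of Visium donor 9 and 1200 in that of Visium-SPG donor 3, and the TTR/FOLR1 region 944 spots in that of Visium donor 7.

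The sections held 9 regions in differing shares. Over the 10 Visium donors, the MBP/MOBP region (myelin genes) took 19.5% ± 10.9 of spots (SD, n = 10), NEUROD6/FIBCD1 (pyramidal neuron genes) 19.0% ± 8.93, AQP4/SLC1A2 (astrocyte and neuropil genes) 17.5% ± 11.7 and GAD1/SLC32A1 (GABA synthesis and transport) 15.4% ± 4.10. Without donor 4, where AQP4/SLC1A2 took 44.8%, its share was 14.4% ± 7.07 (n = 9). CALB1/PPFIA2 (granule neuron genes) took 8.36% ± 7.49 and TESPA1/RXFP1 (cortical neuron genes) 7.83% ± 6.59. CFAP126/PIFO (genes of motile cilia) took 1.64% ± 0.838, TAGLN/ACTA2 (smooth muscle) 1.49% ± 1.07 and TTR/FOLR1 (choroid plexus) 0.884% ± 1.73, or 0.359% ± 0.533 without donor 7 (n = 9). The other 8.42% ± 6.52 lay in cluster 8, which led in no marker list. In donor 2, 0 of 5917 spots were in the CALB1/PPFIA2 region, which allows a share of up to 0.0507%, and in donor 4 the share was 0.405% (Wilson interval 0.313% to 0.525%). These shares depend on how spots were assigned, being 0.0845% and 1.72% with 30 clusters, 0.608% and 1.51% under direct assignment and 10.4% and 10.3% without averaging. Further capture areas of donor 2 were not analysed here. Donor 7 had the highest TTR/FOLR1 share, 5.61% (5.29% to 5.95%). Shares were not tested.

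**Figure D2:**
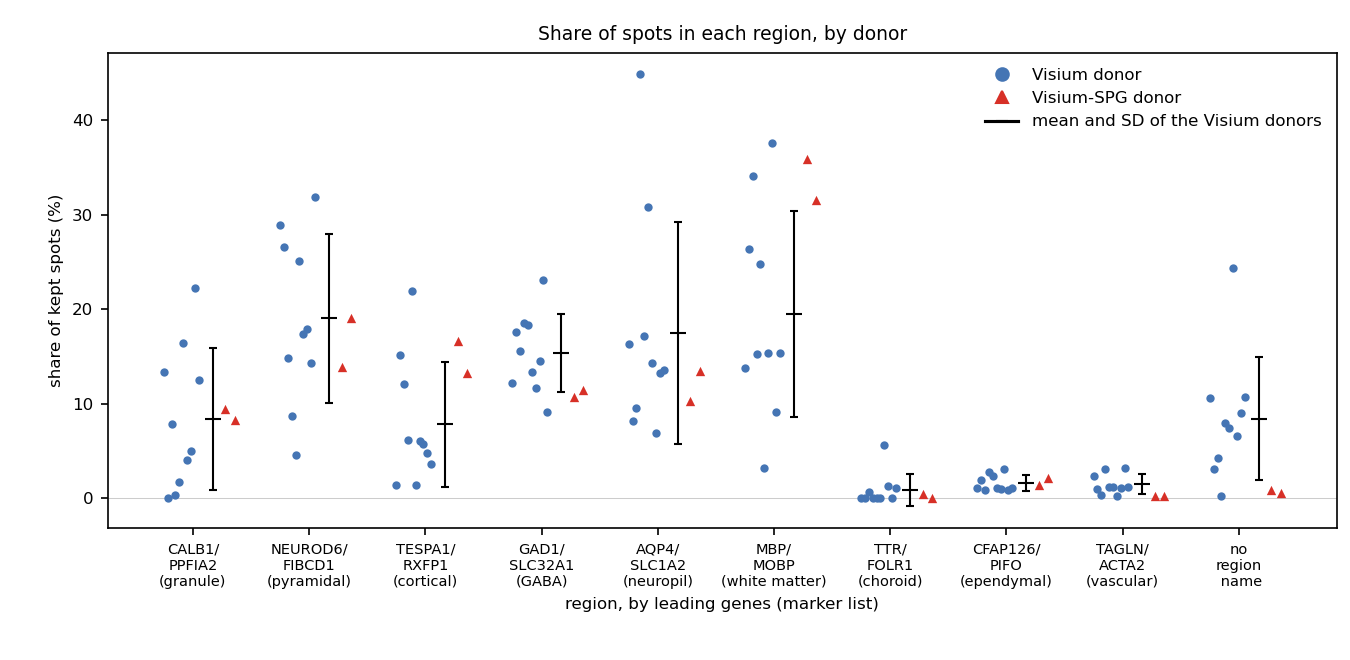
Points give each sample's share of kept spots (%) in each region, as circles for the 10 Visium donors and triangles for the 2 Visium-SPG donors, with the mean and SD of the Visium donors in black. MBP/MOBP shares spread from 3.23% to 37.6% and AQP4/SLC1A2 shares from 6.94% to 44.8% over the Visium donors.

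The CALB1/PPFIA2 region was compared with the NEUROD6/FIBCD1 region in 9 donors to ask which genes mark granule against pyramidal neuron fields. IGSF1, a membrane protein of the immunoglobulin superfamily, stood at 68.0 ± 34.1 CPM against 6.64 ± 2.39 (SD, n = 9), a log2 fold change of 3.45 ± 0.22 (SE). Also higher were CHRNA1 (3.26 ± 0.31), a nicotinic receptor subunit, SEMA3C (2.78 ± 0.24), an axon guidance cue, the chemokine CXCL12 (2.56 ± 0.18) and PPP1R1A (2.47 ± 0.20), a phosphatase inhibitor that stood at 303 ± 154 CPM against 53.6 ± 15.2. LRTM2, the transcription factor RFX3, KCTD4, SHISA9, SLA, BTG3 and THOC3 were higher by 1.96 to 2.39. CABP7, a calcium-binding protein, stood at 6.91 ± 1.98 CPM against 103 ± 42.9, a log2 fold change of -3.96 ± 0.15 with an edgeR adjusted p of 5.38e-10. The adrenergic receptor ADRA1D (-3.75 ± 0.17), CADPS2 (-2.95 ± 0.29), which primes dense-core vesicles, the receptor kinase KIT (-2.95 ± 0.22), CAMK1G (-2.91 ± 0.25) and NELL1 (-2.84 ± 0.27) were lower. CDKN1C, TRHDE, GALNT9, the transcription cofactor LMO4, TRIM36 and CTXND1 were lower by -2.73 to -2.35. Each of these 24 genes had the same direction in all 9 donors, which the naming rule required. Donor 5 had the smallest difference in 17 of them, such as PPP1R1A (0.07), RFX3 (0.19) and CADPS2 (-0.23), and donor 4 in 5. Without donor 5 or donor 4 the calls came to 1323 or 1292 against 1203.

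Of the neuronal lists, the general neuronal and presynaptic ones passed camera with the preset correlation. Of 12 general neuronal genes, 5 were lower in the CALB1/PPFIA2 region, among them the neurofilaments NEFH (-1.87 ± 0.14) and NEFM (-1.07 ± 0.10) and SYT1 (-1.05 ± 0.08), with a camera adjusted p of 4.22e-11, and adjusted p = 0.24 with an estimated correlation. Of 18 presynaptic genes, 4 were lower, SV2B (-1.42 ± 0.14), CPLX1 (-1.18 ± 0.10), STX1A (-1.08 ± 0.14) and RIMS1 (-1.03 ± 0.12), with a camera adjusted p of 1.14e-08, and adjusted p = 0.341 with an estimated correlation. Of 14 neuropeptide genes, PDYN (2.72 ± 0.31), the dynorphin precursor, was higher and 4 were lower, such as ADCYAP1 (-1.67 ± 0.44) and CCK (-1.55 ± 0.27). The list did not pass camera (adjusted p = 0.19). Of 13 neuromodulator receptors, ADRA1A (2.59 ± 0.32) was higher and 4 were lower, such as the muscarinic receptor CHRM3 (-2.35 ± 0.28), the dopamine receptor DRD1 (-2.24 ± 0.37) and the serotonin receptor HTR2A (-1.65 ± 0.21), with a camera adjusted p of 0.0516. Of 10 GABA-A receptor subunits, GABRD (2.4 ± 0.21) was higher and GABRA3 (-1.38 ± 0.17) lower (camera adjusted p = 0.71). The postsynaptic, potassium channel and interneuron lists did not pass camera either (adjusted p = 0.0513, 0.0516 and 0.76), with 0 of 16, 1 of 14 and 1 of 12 genes lower. Adjusted over the list alone, the counts were 5 general neuronal, 4 presynaptic, 5 neuropeptide, 5 neuromodulator and 2 GABA-A receptor genes, and 0, 1 and 1 in the last 3 lists. The 22 ribosomal protein genes had a median of 0.36 with 0 called (camera adjusted p = 5.71e-05, and adjusted p = 0.636 with an estimated correlation). Oligodendrocyte genes had a median of -0.80 with 2 of 16 lower (camera adjusted p = 0.000162, and adjusted p = 0.577 with an estimated correlation). In all, 656 genes were higher and 547 lower of 15158 tested, and without averaging spots over their neighbours 350 genes were called (231 higher and 119 lower).

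**Figure D3:**
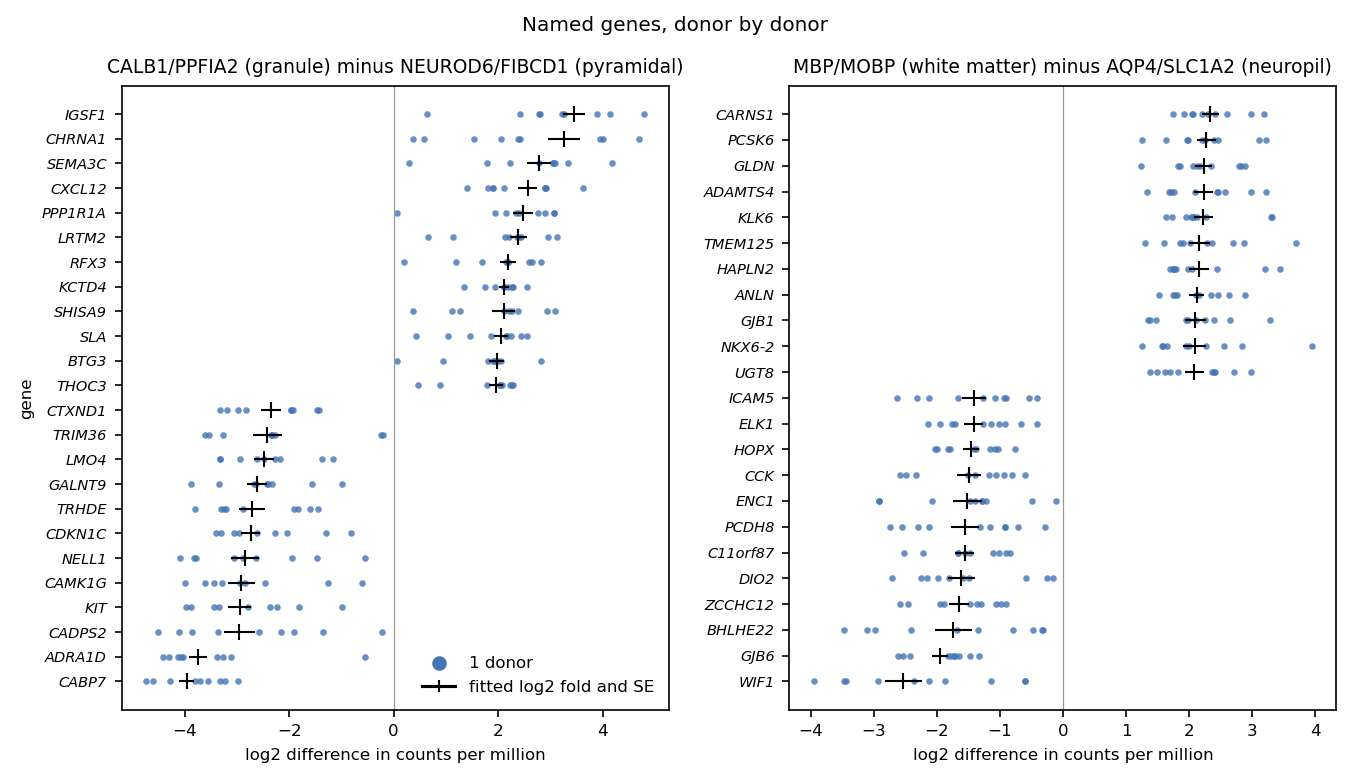
The x axis gives the log2 difference in CPM between 2 regions for 24 genes (left) and 23 (right), with 1 dot per donor (9 donors left, 10 right) and the fitted log2 fold change ± SE in black. CABP7 (-3.96) and IGSF1 (3.45) lie farthest apart on the left, and WIF1 (-2.53) and CARNS1 (2.34) on the right.

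The NEUROD6/FIBCD1 region was compared with the TESPA1/RXFP1 region in 10 donors, that is hippocampal pyramidal against cortical neuron markers. ADRA1D stood at 49.98 ± 25.4 CPM against 7.22 ± 10.5 (SD, n = 10), a log2 fold change of 3.39 ± 0.26 (SE). The cell surface protein CD24 (2.53 ± 0.26), the transcription factor BHLHE22 (2.33 ± 0.17), the activin-type receptor ACVR1C (2.24 ± 0.18), SHISA6 (2.24 ± 0.23), RTP5 (2.10 ± 0.22) and TDRD9 (1.99 ± 0.20) were higher as well. PCDH8, the neuropeptide CARTPT, the exchanger SLC24A3, RSPO3 and HPCA, a calcium sensor at 1029 CPM against 295, were higher by 1.66 to 1.80. RGS4, a regulator of G protein signalling, stood at 101 ± 72.2 CPM against 290 ± 114, a log2 fold change of -1.73 ± 0.25. The transcription factor MEF2C (-1.63 ± 0.13), RPH3A (-1.63 ± 0.14), DPY19L1, FN1 and GABRD (-1.40 ± 0.13) were lower, as were the oligodendrocyte genes HAPLN2, BCAS1, OPALIN, MYRF, LPAR1 and CARNS1, by -1.59 to -1.45.

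Myelin-related genes formed the largest list difference here. Of 16 oligodendrocyte genes, 12 were lower in the NEUROD6/FIBCD1 region (12 adjusted over the list alone), with a median of -1.29 and a camera adjusted p of 3.49e-36, and adjusted p = 0.0321 with an estimated correlation. Of 16 postsynaptic genes, the glutamate receptor GRIA1 (1.21 ± 0.10) was higher (1 adjusted over the list alone), and the list's camera adjusted p was 1.86e-05, with adjusted p = 0.343 with an estimated correlation. Of 12 interneuron genes, KIT (1.66 ± 0.16) was higher and RELN (-1.53 ± 0.20), an extracellular matrix protein, lower (2 adjusted over the list alone), with a camera adjusted p of 0.00516, and adjusted p = 0.189 with an estimated correlation. NR3C2 (1.25 ± 0.09), the mineralocorticoid receptor, was higher among 7 glucocorticoid response genes (1 adjusted over the list alone, camera adjusted p = 0.18), whose median of -0.01 and mean of 0.21 differed in sign. Of 7 genes of immature or cycling cells, NEUROD1 (2.4 ± 0.20) was higher and STMN1 (-1.21 ± 0.14) lower (2 adjusted over the list alone, camera adjusted p = 0.979). The 22 ribosomal protein genes here had a median of -0.31 and 0 calls by edgeR, also 0 adjusted over the list alone (camera adjusted p = 1.86e-05, and adjusted p = 0.638 with an estimated correlation). In all, 244 genes were higher and 421 lower of 14160 tested. In this comparison 366 were called without averaging over neighbours (64 higher and 302 lower).

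The NEUROD6/FIBCD1 region was also compared with the AQP4/SLC1A2 region in 10 donors. MET, a receptor kinase, stood at 50.7 ± 43.1 CPM against 10.4 ± 10.4 (SD, n = 10), a log2 fold change of 2.44 ± 0.21 (SE). The phosphatase DUSP4, RSPO3, NELL1, CCN3, CADPS2, TOMM34, NOS1AP, CAMK1G, SLC24A3 and PLK2 were higher by 1.53 to 1.66. The secreted Wnt modulator SFRP2 (-3.21 ± 0.26) stood at 7.95 ± 6.37 CPM against 68.3 ± 27.4 and RELN (-3.14 ± 0.29) at 9.57 ± 3.50 against 85.6 ± 52.6. The receptor APLNR (-2.47 ± 0.13), LINC00844 (-2.27 ± 0.16), OPALIN (-2.16 ± 0.18), the inhibitory transcription factor ID3 (-2.07 ± 0.18) and FAM107B (-2.06 ± 0.14) were lower, and MYBPC1, CAPN3, ERMN and the urea transporter SLC14A1 by -2 to -1.96.

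Several neuronal lists were higher and several glial lists lower in the NEUROD6/FIBCD1 region than in the AQP4/SLC1A2 region. Of 12 general neuronal genes, 10 were higher, such as ENC1 (1.38 ± 0.18) and the vesicular glutamate transporter SLC17A7 (1.29 ± 0.13), and so were 8 of 18 presynaptic genes, such as SV2B (1.30 ± 0.14), 8 of 16 postsynaptic genes, such as GRIA1 (1.23 ± 0.11), 3 of 14 potassium channels, such as KCNQ5 (1.31 ± 0.18), and 4 of 11 neuromodulator receptors, such as DRD5 (1.45 ± 0.23). Camera gave these lists adjusted p of 1.11e-08, 5.07e-09, 5.43e-06, 7.55e-05 and 0.0219, and adjusted p = 0.177, 0.189, 0.189, 0.189 and 0.178 with an estimated correlation. Lower were 15 of 16 oligodendrocyte genes, 12 of 15 astrocyte genes, such as GFAP (-1.82 ± 0.11) and APOE (-1.51 ± 0.14), 11 of 12 microglial genes, such as the complement gene C1QC (-1.1 ± 0.10), and 7 of 8 genes of oligodendrocyte precursors, such as VCAN (-1.72 ± 0.11). Their camera adjusted p were 2.66e-14, 1.54e-12, 2.64e-09 and 4.85e-09, each with adjusted p = 0.166 with an estimated correlation. Of the 13 mitochondrial-encoded genes 8 were lower (median -1.01), and of 22 ribosomal protein genes 7 (median -0.93), with camera adjusted p of 5.53e-13 and 7.73e-11, and adjusted p = 0.166 and 0.207 with an estimated correlation. Adjusted over the list alone, the counts were 10, 8, 8, 3, 4, 15, 12, 11, 7, 8 and 7 in the order given. Of 12 further interneuron genes 1 was higher and 5 were lower (6 adjusted over the list alone), with a median of -0.87 and a camera adjusted p of 0.018, and adjusted p = 0.178 with an estimated correlation. The neuropeptide list did not pass camera (adjusted p = 0.362). In all, 512 genes were higher and 1631 lower of 14474 tested, and 1218 were called without averaging over neighbours. The higher calls fell to 187 without averaging, 205 under direct assignment, 233 with 30 clusters and 253 with at least 1000 UMIs per spot. Without clusters 13 and 17, of which cluster 13 belongs to the AQP4/SLC1A2 region, 355 were higher and 1589 lower.

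The MBP/MOBP region was compared with the AQP4/SLC1A2 region in 10 donors, setting a myelin-rich field against a neuropil field. CARNS1, which makes the dipeptide carnosine, stood at 447 ± 139 CPM against 92.4 ± 42.6 (SD, n = 10), a log2 fold change of 2.34 ± 0.13 (SE) with an edgeR adjusted p of 3.52e-09. The proteases PCSK6 (2.27 ± 0.15), ADAMTS4 (2.23 ± 0.15) and KLK6 (2.23 ± 0.15), GLDN (2.23 ± 0.13), TMEM125, HAPLN2, ANLN, the gap junction gene GJB1 (2.10 ± 0.17), the transcription factor NKX6-2 and UGT8, an enzyme of myelin lipid synthesis, were higher too. WIF1, a secreted inhibitor of Wnt signalling, stood at 15.9 ± 12.8 CPM against 69.8 ± 34.2, a log2 fold change of -2.53 ± 0.29. It was among the 10 leading genes of cluster 13, which belongs to the AQP4/SLC1A2 region and came mostly from donor 4. The difference ran from -0.599 in donor 9 to -3.95 in donor 4. The astrocyte gap junction gene GJB6 (-1.95 ± 0.13), BHLHE22 (-1.74 ± 0.30), ZCCHC12 (-1.65 ± 0.16), the deiodinase DIO2 (-1.61 ± 0.22) and C11orf87 (-1.56 ± 0.15) were lower, as were PCDH8, ENC1, CCK, HOPX, ELK1 and ICAM5 by -1.55 to -1.41.

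All 16 oligodendrocyte genes outside the panel were higher in the MBP/MOBP region (median 1.91, camera adjusted p = 9.03e-34, and adjusted p = 0.0915 with an estimated correlation). Of 10 GABA-A receptor subunits, 7 were lower, such as GABRB1 (-1.53 ± 0.22) and GABRA2 (-1.39 ± 0.12), and of 16 postsynaptic genes 5, such as DDN (-1.31 ± 0.26), each list with a camera adjusted p of 3.04e-08, and with adjusted p = 0.238 and 0.398 with an estimated correlation. Of 14 neuropeptide genes, 5 were lower, such as PDYN (-1.85 ± 0.23), and of 15 astrocyte genes 2, GJB6 and SLC4A4 (-1.25 ± 0.12), with camera adjusted p of 0.00161 and 3.22e-05, and adjusted p = 0.238 and 0.451 with an estimated correlation. The counts adjusted over the list alone were 16, 7, 5, 5 and 2. The 13 mitochondrial-encoded genes had a median of -0.83 and the 22 ribosomal protein genes one of 0.31, with 0 calls by edgeR in either, also 0 adjusted over the list alone. Their camera adjusted p were 2.11e-05 and 0.00287, and adjusted p = 0.451 and 0.637 with an estimated correlation. In all, 644 genes were higher and 403 lower of 13689 tested, and 1676 were called without averaging over neighbours (834 higher and 842 lower). The lower calls were 759 with 30 clusters, 647 under direct assignment and 645 with at least 1000 UMIs per spot. Cluster 17, which leads with genes of no white matter list, belongs to this region, and without clusters 13 and 17 the count was 1144.

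**Figure D4:**
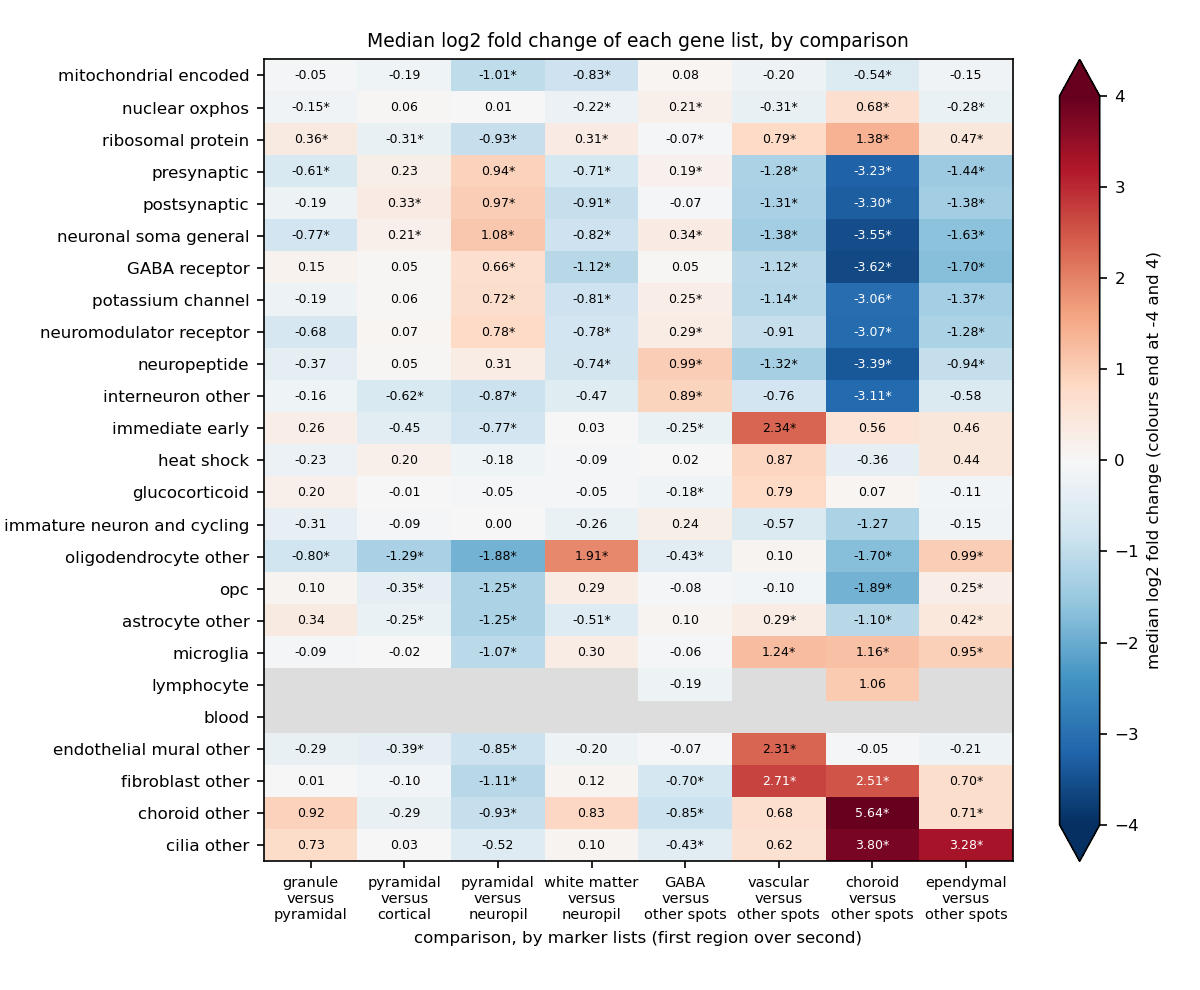
Colours and numbers give the median log2 fold change of each gene list in 8 comparisons, first region over second. An asterisk marks a camera adjusted p under 0.05 with the preset correlation, and grey marks lists with fewer than 4 members tested. Oligodendrocyte genes run from -1.88 to 1.91, and choroid plexus genes reach 5.64 in the TTR/FOLR1 column.

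The TTR/FOLR1 region was compared with all other spots of the 4 donors that held it in number (donors 3, 7, 8 and 10). The sulfate transporter SLC13A4 stood at 951 ± 246 CPM against 2.83 ± 2.31 (SD, n = 4), a log2 fold change of 8.63 ± 0.21 (SE). FBP2 (8.87 ± 0.24), a gluconeogenesis enzyme, the iodide transporter SLC5A5 (8.76 ± 0.22), TCTEX1D4 (8.72 ± 0.24), the tight junction gene CLDN2 (8.71 ± 0.22), the protease KLK11 (8.69 ± 0.22) and the organic anion transporter SLC22A8 (8.62 ± 0.22) were higher. The ion channels TRPV4 and KCNJ13, C14orf180, the melanosome enzyme TYRP1 and LINC01544 were higher by 8.23 to 8.58. Lower were CELF5 at -4.71 ± 0.27, CRYM at -4.65 ± 0.23, RGS4 at -4.61 ± 0.24, GABRB2 at -4.36 ± 0.24, ADCY1 at -4.27 ± 0.23, ELAVL4 at -4.24 ± 0.26 and VSNL1 at -4.20 ± 0.18, and CAMK2N2, BCL11A, SNCB and DIRAS2 by -4.17 to -4.01.

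All 12 general neuronal genes were lower in this region and 17 of 18 presynaptic genes (12 and 17 adjusted over the list alone), with medians of -3.55 and -3.23 and camera adjusted p of 7.29e-10 and 3.28e-10, both with adjusted p = 0.265 with an estimated correlation. Of 13 mitochondrial-encoded genes 4 were lower (4 adjusted over the list alone, median -0.54), with a camera adjusted p of 0.0147, and adjusted p = 0.525 with an estimated correlation. All 10 choroid plexus genes outside the panel were higher (10 adjusted over the list alone, median 5.64), and 8 of 10 cilia genes (8 adjusted over the list alone), such as SPAG17 (5.07 ± 0.25). Camera adjusted p were 5.85e-10 and 4.83e-07, both with adjusted p = 0.265 with an estimated correlation. Of 22 ribosomal protein genes 18 were higher (median 1.38), of 10 fibroblast genes 7, such as FBLN1 (6.11 ± 0.17) and IGFBP7 (5.79 ± 0.17), and of 21 nuclear oxidative phosphorylation genes 5, such as UQCRB (1.87 ± 0.14), with camera adjusted p of 4.39e-11, 2.47e-06 and 0.000108, and adjusted p = 0.265, 0.265 and 0.476 with an estimated correlation. Of 12 microglial genes 7 were higher, such as C1QA (1.71 ± 0.16), and 2 lower, CX3CR1 (-1.93 ± 0.23) and P2RY12 (-1.30 ± 0.53), with a camera adjusted p of 0.0109, and adjusted p = 0.476 with an estimated correlation. Of 4 lymphocyte genes PTPRC (2.12 ± 0.24) and NKG7 (1.70 ± 0.56) were higher and CD8A (-1.69 ± 0.54) lower (camera adjusted p = 0.386). The serotonin receptor HTR2C (4.50 ± 0.17) was higher while 11 of the other 12 neuromodulator receptors were lower. Adjusted over the list alone, the counts of these 5 lists were 18, 7, 5, 9 and 3, and 12 for the receptors. In all, 3204 genes were higher and 4170 lower of 17819 tested, and assigning spots directly by their highest score gave 894 (763 higher and 131 lower).

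The TAGLN/ACTA2 region was compared with all other spots in 10 donors. MYH11, the smooth muscle myosin heavy chain, stood at 294 ± 104 CPM against 4.52 ± 1.44 (SD, n = 10), a log2 fold change of 6.02 ± 0.14 (SE). The matrix proteins MGP (5.36 ± 0.18), MFAP4 (4.93 ± 0.20) and COL6A2 (4.16 ± 0.18), the calcium-binding S100A4 (4.96 ± 0.17), CRIP1 (4.67 ± 0.12), the tropomyosin TPM2 (4.55 ± 0.12), MUSTN1 (4.28 ± 0.13) and CEMIP (4.20 ± 0.17), which breaks down hyaluronan, were higher. So were the globins HBA2 (4.18 ± 0.23), HBB (4.14 ± 0.23) and HBA1 (4.03 ± 0.24), of which HBA1 and HBA2 have near-identical sequences that counting could split. Lower were NELL1 (-1.92 ± 0.21), CARTPT (-1.86 ± 0.17), MIR7-3HG (-1.82 ± 0.19), SEZ6 (-1.78 ± 0.18), the glutamate receptor GRM5 (-1.78 ± 0.20) and SLIT1 (-1.76 ± 0.15), and CABP7, ANKRD33B, HPCA, KCNIP2 and GALNT9 by -1.75 to -1.71.

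Immediate early genes, which respond fast to stimulation, were higher in this region, with 8 of 10 called (8 adjusted over the list alone) and the 3 largest at NR4A1 (3.58 ± 0.20), DUSP1 (3.35 ± 0.21) and FOS (3.09 ± 0.22). The list's median was 2.34 and its camera adjusted p 2.65e-06, with adjusted p = 0.153 with an estimated correlation. Of 22 ribosomal protein genes 2 were higher (2 adjusted over the list alone, median 0.79), with a camera adjusted p of 2.23e-18, and adjusted p = 0.153 with an estimated correlation. All 12 general neuronal and 15 of 18 presynaptic genes were lower (12 and 15 adjusted over the list alone), with camera adjusted p of 6.32e-11 and 1.11e-12, both with adjusted p = 0.153 with an estimated correlation. Of 12 further interneuron genes 1 was higher and 3 were lower (4 adjusted over the list alone, camera adjusted p = 0.286). Of 8 heat shock genes, HSPB1 (1.96 ± 0.13), HSPA1A (1.74 ± 0.17) and HSPA1B (1.62 ± 0.17) were higher and HSPH1 (-1.13 ± 0.12) lower (4 adjusted over the list alone, camera adjusted p = 0.211), where HSPA1A and HSPA1B are near-identical copies. All 10 fibroblast genes were higher, 10 of 12 endothelial and mural genes, such as NOTCH3 (3.19 ± 0.13) and PECAM1 (2.77 ± 0.19), and 8 of 12 microglial genes, such as C1QA (1.66 ± 0.14) and CD74 (1.45 ± 0.12). Adjusted over the list alone, these counts were 10, 10 and 8, and camera adjusted p were 2.16e-12, 2.16e-12 and 4.88e-08, each with adjusted p = 0.153 with an estimated correlation. In all, 1672 genes were higher and 1310 lower of 15593 tested, and 889 were called without averaging over neighbours (853 higher and 36 lower). Under direct assignment 789 were higher and 43 lower, by the DESeq2 Wald test 841 were lower and with 30 clusters 663. Scaling by DESeq2 size factors raised the log2 fold changes of the 24 named genes by a median of 0.12.

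The GAD1/SLC32A1 region was compared with all other spots in 10 donors to ask which further genes accompany the inhibitory neuron markers. Cluster 6, the largest of this region's clusters with 8509 spots, led with PVALB, DEFB1, PPP1R17 and CHRNA2. These were also among the 10 leading genes of cluster 17, which was placed in the MBP/MOBP region. TAC1, the substance P precursor, stood at 506 ± 316 CPM against 93.5 ± 29.99 (SD, n = 10), a log2 fold change of 2.23 ± 0.18 (SE). CRHBP (1.81 ± 0.17), which binds corticotropin-releasing hormone, the neuropeptides NPY (1.77 ± 0.26) and CORT (1.47 ± 0.12), the phosphatase PTPRT (1.25 ± 0.13), RCAN2 (1.15 ± 0.10), the granin SCG2 (1.1 ± 0.12), NEFH (1.06 ± 0.10), VSTM2A (1.03 ± 0.09) and RAB3B (1.01 ± 0.10) were higher. ECRG4 (-1.63 ± 0.35), which is also on the choroid plexus list, was the only lower gene that met the naming rule. It stood at 7.89 ± 4.77 CPM against 51.0 ± 113. Of 14 neuropeptide genes 7 were higher, also TAC3 (1.90 ± 0.18), PENK (1.14 ± 0.19) and CRH (1.06 ± 0.11), with a camera adjusted p of 3.89e-16, and adjusted p = 0.0253 with an estimated correlation. Of 12 further interneuron genes 5 were higher, the transcription factors DLX5 (1.62 ± 0.17), LHX6 (1.5 ± 0.10), DLX1 (1.46 ± 0.12) and DLX2 (1.32 ± 0.17) and NXPH1 (1.43 ± 0.11), with a camera adjusted p of 2.2e-20, and adjusted p = 0.0132 with an estimated correlation. Of 7 choroid plexus genes 3 were lower, such as SLC13A4 (-5.01 ± 0.39), and of 9 cilia genes 3, such as CAPS (-1.44 ± 0.22), with camera adjusted p of 5.92e-06 and 3.62e-05, and adjusted p = 0.145 and 0.114 with an estimated correlation. With adjustment over the list alone, the counts were 7, 5, 3 and 3. The other spots included the TTR/FOLR1 region, where SLC13A4 stood at 951 CPM (n = 4), and the CFAP126/PIFO region, where CAPS stood at 342. The lower choroid plexus and cilia genes therefore describe the spots compared against as well as the GAD1/SLC32A1 region. The 7 glucocorticoid response genes had 0 calls by edgeR, also 0 adjusted over the list alone, with a median of -0.18 (camera adjusted p = 0.0181, and adjusted p = 0.114 with an estimated correlation). In this region the 22 ribosomal protein genes had a median of -0.07 and 0 calls by edgeR, also 0 adjusted over the list alone (camera adjusted p = 0.015, and adjusted p = 0.694 with an estimated correlation). In all, 124 genes were higher and 106 lower of 16623 tested. Without the donor block 93 were higher and 29 lower, and 383 genes were called without averaging over neighbours (237 higher and 146 lower).

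Visium-SPG was compared with Visium over all kept spots of donors 3 and 8, which were measured by both assays, to ask how the assays differ. The sections were not the same ones and their region shares differed, so assay and section cannot be told apart here. TESPA1/RXFP1 took 16.7% and 13.3% of the Visium-SPG spots of donors 3 and 8, against 12.1% and 5.78% in Visium. TTR/FOLR1 took 0.4445% and 0.063%, against 0.655% and 1.33%. MALAT1, a long noncoding RNA of the nucleus, stood at 6557 ± 1964 CPM in Visium-SPG against 409 ± 281 (SD, n = 2), a log2 fold change of 4.16 ± 0.51 (SE). CCDC144A (5.49 ± 0.57), ANKRD18A (5.19 ± 0.44), SOGA3 (5 ± 0.19), the histone gene HIST1H4C (4.86 ± 0.39), the transcription factor ZBTB20 (4.56 ± 0.36), ANKRD36C (4.56 ± 0.38), CCDC7 (3.96 ± 0.36), CEP290 (3.93 ± 0.19), a protein of the ciliary base, BDP1 (3.70 ± 0.15), ANKRD26 (3.63 ± 0.16) and the noncoding KCNQ1OT1 (3.63 ± 0.11) were higher, and ANKRD36C and CCDC144A have close copies that counting could split. SNHG25 (-2.27 ± 0.11), CSKMT (-2.10 ± 0.11), the inflammasome sensor NLRP1 (-1.93 ± 0.10), the glycolysis enzyme ALDOA (-1.74 ± 0.10), CERCAM (-1.46 ± 0.10), the complement gene C1QB (-1.35 ± 0.09), SNHG9, SERPINF1 and HAPLN2 were lower. So were the globins HBB (-1.69 ± 0.42), HBA2 (-1.59 ± 0.30) and HBA1 (-1.49 ± 0.32).

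Of 12 microglial genes, 8 were lower in Visium-SPG, such as FCER1G (-1.32 ± 0.13), C1QA (-1.21 ± 0.09) and CSF1R (-1.21 ± 0.09), and P2RY12 (1.33 ± 0.18) was higher. The list's median was -1.08 and its camera adjusted p 1.37e-08, with adjusted p = 0.904 with an estimated correlation. Of 25 lists tested over all spots, 7 passed camera with the preset correlation and 0 with an estimated one, and only the microglial list among them is described here. Of 4 blood genes 3 were lower (camera adjusted p = 0.0673), of 10 cilia genes 4 were higher, such as HYDIN (2.32 ± 0.13), with a camera adjusted p of 0.0732, and of 9 genes of immature or cycling cells 3, MKI67 (3.08 ± 0.56), TOP2A (3.05 ± 0.37) and SOX4 (1.13 ± 0.11), with a camera adjusted p of 0.15. Counts adjusted over the list alone were 9, 3, 4 and 3. The 8 lymphocyte genes had 0 calls by edgeR, also 0 adjusted over the list alone (camera adjusted p = 0.582). In all, 2354 genes were higher and 619 lower of 21833 tested. These calls rest on 2 donors, so the fit estimated each gene's spread largely from other genes. The same holds for the comparisons of the assays within regions. The lower calls fell to 347 by the DESeq2 Wald test and to 247 without the donor block. Among genes with a log2 CPM of at least 5, those with long genomic spans were called higher more often, 23.1% in the bin of the longest spans against 1.81% in the shortest. The file headers name Cell Ranger for the Visium areas and Space Ranger for the Visium-SPG areas. The submitters' processing notes name Space Ranger, so whether the program changed with the assay is unsettled.

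In the MBP/MOBP region, compared as clusters 2 and 16 since cluster 17 held no white matter marker among its leading genes, 2593 genes were higher and 545 lower in Visium-SPG. With all 3 clusters the calls were 2593 and 501 of 17318 tested, led by CCDC144A (5.91 ± 0.45), ANKRD18A (5.82 ± 0.33), ANKRD36C (5.35 ± 0.35) and MALAT1 (4.72 ± 0.41), with ANKRD36 (4.27 ± 0.15) and GOLGA4 (4.15 ± 0.17), a Golgi protein, higher as well. SNHG25 (-2.07 ± 0.11), CSKMT (-2 ± 0.09), PCP4 (-1.42 ± 0.24), MYO15B (-1.34 ± 0.09), HID1 (-1.29 ± 0.08), TMEM235 (-1.23 ± 0.09) and LENG8 (-1.19 ± 0.09) were lower. Of 13 mitochondrial-encoded genes 5 were higher in this region (5 adjusted over the list alone), such as MT-ATP8 (1.91 ± 0.17) and MT-CO1 (1.49 ± 0.24), with a camera adjusted p of 0.0199, and adjusted p = 0.976 with an estimated correlation. Of 12 microglial genes there 1 was higher and 0 were lower (1 adjusted over the list alone), while the list lay lower, with a median of -0.54 and a camera adjusted p of 0.0323, and adjusted p = 0.976 with an estimated correlation. In the AQP4/SLC1A2 region 1727 genes were higher and 324 lower of 15371 tested, and without cluster 13, 1121 and 229. There GOLGB1 (3.92 ± 0.16), TRIP11 (3.64 ± 0.14) and ANKRD12 (3.59 ± 0.16) were higher beside CCDC144A (5.14 ± 0.30). IFI27 (-1.26 ± 0.16), RPS10 (-1.25 ± 0.11) and the antigen presentation genes HLA-DPA1 (-1.25 ± 0.13), HLA-DRB1 (-1.19 ± 0.13) and HLA-DRA (-1.19 ± 0.13) were lower, and 8 of 12 microglial genes (9 calls adjusted over the list alone, P2RY12 the higher one), with a camera adjusted p of 1.55e-06, and adjusted p = 0.994 with an estimated correlation. The 13 mitochondrial-encoded genes had 0 calls by edgeR there, also 0 adjusted over the list alone, with a median of -0.08 (camera adjusted p = 0.932). Of 24 lists tested in each region, camera with the preset correlation called 4 in MBP/MOBP and 5 in AQP4/SLC1A2, not all of which are described here. With an estimated correlation it called 0 in either. By the Wald test 254 genes were lower in MBP/MOBP and 103 in AQP4/SLC1A2, and without the donor block 262 and 152. The contrast of MBP/MOBP to AQP4/SLC1A2 differed between the assays in 1 of 17624 genes by edgeR, the mitochondrial-encoded MT-ND6, with 1697 at an unadjusted p under 0.05 and 2 residual degrees of freedom.

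**Figure D5:**
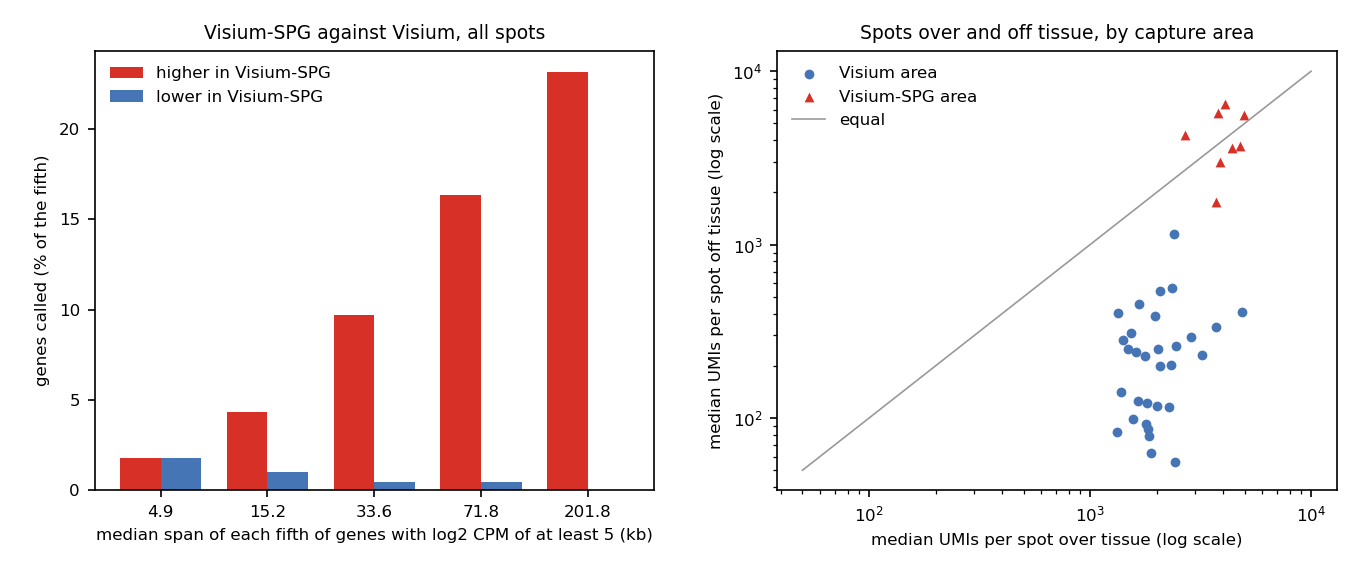
Left, bars give the percentage of genes called higher or lower in Visium-SPG in each of 5 equal bins of genomic span (median span in kb), among tested genes with a log2 CPM of at least 5. Right, each point is a capture area with its median UMIs per spot over tissue (x, log scale) and off tissue (y, log scale). Called higher genes run from 1.81% to 23.1% over the bins, and the off-tissue medians of Visium-SPG areas from 1756 to 6505.5 UMIs against 56 to 1156 in Visium areas.

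Across the 12 comparisons, the median, the mean and the camera direction of a list differed in sign in 33 of 282 tests. These were between the NEUROD6/FIBCD1 and TESPA1/RXFP1 regions the GABA-A receptor, glucocorticoid response and immature or cycling lists, and the latter pair again against AQP4/SLC1A2. In MBP/MOBP they were the immediate early, glucocorticoid response and fibroblast lists, in TTR/FOLR1 the endothelial and mural list, in TAGLN/ACTA2 the precursor list and in GAD1/SLC32A1 the heat shock list. Between the assays they were the interneuron, heat shock and precursor lists in all 3 comparisons, the ribosomal list over all spots, the endothelial and mural list in both regions, and the GABA-A receptor, potassium channel, glucocorticoid response and choroid plexus lists in AQP4/SLC1A2. Between clusters 4 and 10 and clusters 14 and 18 they were the presynaptic, general neuronal, potassium channel, neuropeptide, microglial and cilia lists.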

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

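In this part, the tests restricted to genes with a log2 CPM of at least 5, the difference of a region contrast between the assays, and the comparisons of CFAP126/PIFO and of clusters 4 and 10 were chosen only after results had been seen. The other tests were set beforehand, as were the label swaps of those 2 added comparisons.

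More genes were called higher in Visium-SPG than in Visium (2354) than lower (619). More power from the larger Visium-SPG totals is argued against, since thinning those sums to the Visium totals left 2214 genes higher over all tested genes against 2354 before. Of these, 2161 were shared. Thinning keeps each gene's expected share of UMIs, so it cannot address a bias tied to depth per spot. Among genes with a log2 CPM of at least 5, those called higher had a median span 3.03 times that of genes not called (90366 against 29780 bp, permutation p = 0.0001, the smallest that 10000 permutations can give), so a bias towards long genes is a candidate explanation that this test cannot settle. Over all genes the ratio was 2.62, but a span was known for 73.6% of the higher genes, too few for that test to count. Also open is the counting program, since by the file headers 0 groups held areas of both programs and assay and program cannot be told apart for these genes. The sections also differed in their region shares, though 2593 genes were still higher within the MBP/MOBP region and 1727 within AQP4/SLC1A2. Biological explanations were not tested.

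Of the 619 genes lower in Visium-SPG, many might have lost reads to overlapping genes if the programs treated shared reads differently. Among the 42 of them with a log2 CPM of at least 5, the odds ratio of overlapping another gene was 0.606 against genes not called (Fisher's exact p = 0.113). No excess of overlap was seen there. Overlap was counted without regard to strand, so this test cannot tell whether reads were shared. Over all genes the odds ratio was 0.682, but a span was known for 65.8% of the lower genes, too few for that test to count. Shared reads and the counting program both stay open.

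Spots off tissue, which no comparison used, held a median of 4003 UMIs over the 8 Visium-SPG areas (areas from 1756 to 6505.5), against 231.5 in the Visium areas (56 to 1156). Spots at 3 or more spot pitches from tissue held 0.844 of the UMIs of those next to it (median over areas), with areas from 0.480 to 1.05. By the limit set beforehand this median would argue against spread of RNA from nearby tissue. Spread is left undecided here, a departure from that limit, because the areas differed so widely. Tissue left out of the tissue mask may account for part of it, since 63.9% of those far spots (338 of 529) reached the lower quartile of the spots over tissue in their area, with areas from 0% to 100%, against 0.517% in Visium areas. Of the 79 Visium spots that did, 13, 57 and 2 lay in 3 areas of donor 10, which were 56.5%, 23.1% and 11.1% of the far spots there. No image was used here and no biological explanation was tested.

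The contrast of the MBP/MOBP to the AQP4/SLC1A2 region differed between Visium-SPG and Visium in MT-ND6, a mitochondrial-encoded gene, by 1.09 on the log2 scale (edgeR adjusted p = 0.0309). It was the 1 gene called by edgeR of 17624 tested, with 1697 at unadjusted p < 0.05.

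In 19 of 210 groups of 4 to 10 donors tested, 1 donor lay far from the others. Chance alone gives about 1 in 20 such groups if values are independent and normally spread. Here the genes of a comparison share donors and several flagged values come from 0 UMIs, so no excess over chance can be read from this count. Visium donor 7 had 5.61% of spots in the TTR/FOLR1 region (others 0% to 1.33%) and 24.4% in the unnamed cluster 8 (others 0.228% to 10.7%). Visium donor 4 had a median of 3675.5 UMIs per spot (others 1646 to 2509).

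The other 16 cases are log2 differences of named genes in 1 Visium donor. Some donors had the smallest difference in many of the named genes of a comparison. Donor 5 had it in 17 of 24 for CALB1/PPFIA2 against NEUROD6/FIBCD1 and in 12 of 24 for NEUROD6/FIBCD1 against TESPA1/RXFP1, donor 9 in 14 of 22 for NEUROD6/FIBCD1 against AQP4/SLC1A2 and donor 7 in 18 of 23 for TTR/FOLR1. Without that donor the calls came to 1323, 758, 2383 and 6766. Between the CALB1/PPFIA2 and NEUROD6/FIBCD1 regions of donor 5, PPP1R1A differed by 0.0715 (others 1.94 to 3.07) and ADRA1D by -0.55 (others -4.41 to -3.11), the latter from 3 UMIs in the former region, a ratio of 0.674 with a counting interval of 0.124 to 2.42. CARNS1 in NEUROD6/FIBCD1 against TESPA1/RXFP1 differed by -2.65 in donor 6 (others -1.73 to -0.81), and CAPN3 in NEUROD6/FIBCD1 against AQP4/SLC1A2 by -0.44 in donor 9 (others -2.79 to -1.66). In the TTR/FOLR1 region against other spots, TRPV4 differed by 7.28 in donor 7 (others 8.66 to 8.87) and VSNL1 by -5.05 in donor 3 (others -4.05 to -3.88). There CELF5 had 0 UMIs in donor 3 and ELAVL4 0 in donor 8, at least 36.4-fold and 25.8-fold lower at a floor of 3 counts per donor, and their log2 differences of -9.71 and -9.72 depend on the prior count and are no bounds. In the TAGLN/ACTA2 region, MYH11 differed by 6.98 in donor 3 (others 5.33 to 6.13) and CEMIP by 2.15 in donor 7 (others 3.60 to 5.06). There NELL1 and GALNT9 in donor 7 and CARTPT in donor 3 had 0 UMIs, at least 1.09-fold, 1.39-fold and 1.14-fold lower, and their log2 differences of -9.04, -9.40 and -8.30 are likewise no bounds. ECRG4 in the GAD1/SLC32A1 region differed by -4.39 in donor 7 (others -2.10 to -0.0047). The other spots of donor 7 held ECRG4 at 296 CPM and included 1032 TTR/FOLR1 spots. In the CFAP126/PIFO region, CCN3 in donor 6 and CPNE4 in donor 7 had 0 UMIs, at least 2.16-fold and 3.30-fold lower, with log2 differences of -8.50 and -8.63 that are no bounds either.

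Region labels were swapped within donors in 41 arrangements, the real one included, and only 1 of the 41, the real one, called as many genes by edgeR in 8 comparisons. The regions were drawn from the expression of the same spots, so their labels differ by construction and the swaps say nothing about chance. The real count and the highest of the others were 1203 and 1104 for CALB1/PPFIA2 against NEUROD6/FIBCD1, 665 and 328 for NEUROD6/FIBCD1 against TESPA1/RXFP1, 2143 and 829 for NEUROD6/FIBCD1 against AQP4/SLC1A2, 1047 and 317 for MBP/MOBP against AQP4/SLC1A2, 2982 and 2143 for TAGLN/ACTA2, 230 and 30 for GAD1/SLC32A1, 2932 and 1766 for CFAP126/PIFO, and 472 and 366 for clusters 4 and 10 against clusters 14 and 18. The highest other arrangement swapped 2 donors in each of these 8 and left the others as they were. For TTR/FOLR1 the 8 possible arrangements of 4 donors are too few for a share under 0.05, with 7374 genes in the real one and 0 as the highest of the others.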

How the results depend on the processing

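The counts without clusters 13 and 17, the CFAP126/PIFO comparison and that of clusters 4 and 10 with clusters 14 and 18 were chosen after the data had been seen, and the other alternatives were set beforehand. All 12 total counts of called genes stayed within 1.5 times of the value reported under DESeq2 size factors, the DESeq2 Wald test, 30 clusters, at least 100 spots per donor and region, Visium-SPG spots added and no mitochondrial-encoded genes, where these could be run. The higher and lower calls taken apart moved more. In the TAGLN/ACTA2 region the Wald test called 1731 higher and 841 lower, against 1672 and 1310, and with 30 clusters 663 were lower. For Visium-SPG against Visium over all spots, in MBP/MOBP and in AQP4/SLC1A2, the lower calls were 619, 501 and 324 as reported, 347, 254 and 103 by the Wald test and 247, 262 and 152 without the donor block. For NEUROD6/FIBCD1 against AQP4/SLC1A2 the higher calls were 512 as reported and 233 with 30 clusters, 205 under direct assignment and 253 with at least 1000 UMIs, and for MBP/MOBP the lower calls were 403 and 759, 647 and 645.

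No named gene reversed its direction, though the naming rule had required the same direction in every donor compared. The side with more calls changed in some comparisons. CFAP126/PIFO had 1343 higher and 1589 lower as reported, and 1767 and 1257 with DESeq2 size factors, 1598 and 1097 by the Wald test, 2443 and 1480 without a filter on low counts and 1147 and 1092 with 30 clusters. CALB1/PPFIA2 had 1023 and 1076 without that filter and 681 and 691 with at least 1000 UMIs, MBP/MOBP 834 and 842 without averaging, TTR/FOLR1 763 and 131 under direct assignment, and GAD1/SLC32A1 121 and 132 or 123 and 130 with 1 donor left out. Without a fold threshold it changed for NEUROD6/FIBCD1 against TESPA1/RXFP1 (2253 and 2221) and against AQP4/SLC1A2 (4990 and 4794) and for TAGLN/ACTA2 (2961 and 3623).

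Without a filter on low counts, which tested more genes, the counts were 2099 for CALB1/PPFIA2 against NEUROD6/FIBCD1, 1314 for NEUROD6/FIBCD1 against TESPA1/RXFP1, 3316 for NEUROD6/FIBCD1 against AQP4/SLC1A2, 1774 for MBP/MOBP against AQP4/SLC1A2, 532 for GAD1/SLC32A1 (186 higher and 346 lower) and 889 between the cluster pairs. Without a fold threshold, which adds small changes by construction, the counts were 7605, 4474, 9784 and 6450 in the first 4 of these, 6584 for TAGLN/ACTA2, 3050 for GAD1/SLC32A1, 7734 for CFAP126/PIFO, 2727 between the cluster pairs, and 9302, 9392 and 6093 for Visium-SPG against Visium over all spots, in MBP/MOBP and in AQP4/SLC1A2. Without averaging over neighbours the counts were 350, 366, 1218 and 1676 in the first 4, 889 for TAGLN/ACTA2 (853 higher and 36 lower), 383 for GAD1/SLC32A1 and 234 for CFAP126/PIFO (211 higher and 23 lower). Under direct assignment they were 894 for TTR/FOLR1, 832 for TAGLN/ACTA2 (789 higher and 43 lower) and 644 for CFAP126/PIFO. For GAD1/SLC32A1 the count was 122 without the donor block and 390 with only spots whose leading score led by 0.5, and leaving out the block changed no other total by over 1.5 times. Without clusters 13 and 17 Visium-SPG against Visium in AQP4/SLC1A2 gave 1350. Except where a construction is named, the cause was not tested.

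Mean shares of spots moved by more than the SD over donors in these cases. The TTR/FOLR1 share was 4.32% under direct assignment. The CFAP126/PIFO share was 0.0% with 12 clusters and 4.88% under direct assignment. The GAD1/SLC32A1 share was 4.78% without averaging, 9.81% with 12 clusters, 8.60% with 30, 5.14% with at least 1000 UMIs and 11.3% with a leading score by 0.5. The TAGLN/ACTA2 share was 4.80% without averaging, 5.67% under direct assignment and 3.07% with a leading score by 0.5. The unnamed share was 23.0% without averaging, 15.0% with 12 clusters, 16.2% with 30 and 20.9% with at least 1000 UMIs. The cause was not tested.

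With an estimated correlation, camera called 0 lists in 10 of the 12 comparisons, 1 in NEUROD6/FIBCD1 against TESPA1/RXFP1, where the preset correlation called 8, and 2 in GAD1/SLC32A1, where it called 14. The cause was not tested.

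Leaving out each donor in turn gave 1110 to 1323 genes for CALB1/PPFIA2 against NEUROD6/FIBCD1, 573 to 758 for NEUROD6/FIBCD1 against TESPA1/RXFP1, 1938 to 2405 against AQP4/SLC1A2, 852 to 1162 for MBP/MOBP, 6766 to 7376 for TTR/FOLR1, 2447 to 3107 for TAGLN/ACTA2, 195 to 265 for GAD1/SLC32A1, 2610 to 3056 for CFAP126/PIFO and 393 to 536 between the cluster pairs. Leaving out donor 3 or 8 from the assay comparisons would leave 1 pair and no residual degrees of freedom, so it gave fold changes of named genes with no test, of which 134 kept their direction at a log2 difference of at least 1 and 10 kept the direction alone. Of the tested values of named genes, 1863 kept their direction and call with a donor left out and 9 kept the direction alone, and under the other settings 3548 and 104, of which 44 came without averaging over neighbours and 37 under direct assignment. Depth was lowest in the TAGLN/ACTA2 region, with as few as 46 spots and 78551 UMIs in a donor, and the CALB1/PPFIA2 region had as few as 57 spots in a donor.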

Other observations

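The 2 comparisons in this part were added after the data had been seen, and their tests and named genes follow the rules fixed beforehand. The CFAP126/PIFO region, with 0.879% to 3.11% of spots per Visium donor, was compared with all other spots in 10 donors. CAPS, a calcium-binding protein of ciliated cells, stood at 342 ± 192 CPM against 17.8 ± 8.83 (SD, n = 10), a log2 fold change of 4.27 ± 0.18 (SE). ANXA1 (3.72 ± 0.16), the protease inhibitor SERPINA3 (2.72 ± 0.17), C1orf194 (2.66 ± 0.18), the hyaluronan receptor CD44 (2.45 ± 0.11), SFRP2 (2.26 ± 0.15), C9orf24 (2.20 ± 0.15), AEBP1 (2.06 ± 0.12), the lipid transfer protein PLTP (2.02 ± 0.12), APLNR (1.98 ± 0.12), TPPP3 (1.96 ± 0.10) and HBA2 (1.92 ± 0.13) were higher. The GABA-A receptor subunits GABRQ (-2.60 ± 0.25) and GABRA3 (-2.22 ± 0.20), HAPLN4 (-2.25 ± 0.21), the netrin receptor UNC5A (-2.24 ± 0.17), RTN4RL2 (-2.19 ± 0.20) and the growth factor BDNF (-2.18 ± 0.24) were lower, as were RGS4, CRYM, DIRAS2, CCN3, CPNE4 and MAL2 by -2.13 to -1.98.

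All 10 cilia genes were higher in the CFAP126/PIFO region (10 adjusted over the list alone), such as CFAP299 (4.49 ± 0.33) and SPAG17 (3.8 ± 0.31), with a median of 3.28 and a camera adjusted p of 2.28e-08, and adjusted p = 0.166 with an estimated correlation. Of 16 oligodendrocyte genes 8 were higher, such as CRYAB (1.31 ± 0.09), of 15 astrocyte genes 3, GFAP (1.69 ± 0.09), S100B (1.43 ± 0.08) and SOX9 (1.37 ± 0.11), and of 12 microglial genes 5, such as HLA-DRA (1.19 ± 0.10). All 18 presynaptic genes were lower, such as STX1A (-1.96 ± 0.16). Camera adjusted p were 3.53e-14, 1.2e-06, 2.54e-07 and 1.51e-14, each with adjusted p = 0.166 with an estimated correlation, and adjusted over the list alone the counts were 8, 3, 5 and 18. Of 14 neuropeptide genes NTS (2.87 ± 0.23), the neurotensin precursor, was higher in 8 of 10 donors and 6 were lower (7 adjusted over the list alone), with a camera adjusted p of 0.000621, and adjusted p = 0.166 with an estimated correlation. The 22 ribosomal protein genes had a median of 0.47 and 0 calls by edgeR, also 0 adjusted over the list alone (camera adjusted p = 1.51e-14, and adjusted p = 0.166 with an estimated correlation). In all, 1343 genes were higher and 1589 lower of 15578 tested. DESeq2 size factors raised the log2 fold changes of the 24 named genes by a median of 0.13 and gave 1767 higher and 1257 lower, the DESeq2 Wald test 1598 and 1097. Without averaging over neighbours 234 genes were called (211 higher and 23 lower), and under direct assignment 644 (590 and 54).

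Within the NEUROD6/FIBCD1 region, clusters 4 and 10, where the panel gene FIBCD1 is among the leading genes, were compared with clusters 14 and 18, where TSPAN18 and NECTIN3 are, in 10 donors. MET and CCN3 were already among the 10 leading genes of cluster 4 when the clusters were picked, so their values describe the split. The receptor kinase MET stood at 94.5 ± 47.9 CPM against 15.3 ± 22.3 (SD, n = 10), a log2 fold change of 3.97 ± 0.42 (SE). CCN3 (2.27 ± 0.20), PARM1 (2.26 ± 0.25), PEX5L (2.07 ± 0.25), which traffics HCN channels, and the transcription factors BHLHE40 (1.87 ± 0.17) and BCL11B (1.83 ± 0.21) were higher, as were CTXND1, RASL10A, TTC9, SLC35F1, RIPOR2 and the calcium release channel ITPR1 by 1.36 to 1.72. B3GAT2 (-2.51 ± 0.30), a glucuronyl transferase, the protease KLK7 (-2.12 ± 0.28), the RNA-binding ELAVL2 (-1.79 ± 0.22), ARHGEF17 (-1.72 ± 0.18), SPOCK1 (-1.60 ± 0.26) and DOCK10 (-1.57 ± 0.17) were lower, with COX7A1, PTPRK, CA10, SYT13, GFAP and AQP1 at -1.56 to -1.23. Of 10 GABA-A receptor subunits 3 were higher, such as GABRB2 (1.34 ± 0.15) and GABRA3 (1.29 ± 0.11), and of 16 postsynaptic genes 2, such as DDN (1.33 ± 0.24), with camera adjusted p of 9.19e-06 and 3.06e-05, and adjusted p = 0.135 and 0.207 with an estimated correlation. Of 11 neuromodulator receptors DRD5 (2.32 ± 0.24), HRH3 (1.54 ± 0.22) and HTR2A (1.46 ± 0.22) were higher and OPRM1 (-1.02 ± 0.27) lower, with a camera adjusted p of 0.00428, and adjusted p = 0.201 with an estimated correlation. Adjusted over the list alone, the counts were 3, 2 and 4. Between these clusters the 13 mitochondrial-encoded genes had a median of -0.22 and 0 calls by edgeR, also 0 adjusted over the list alone (camera adjusted p = 0.0177, and adjusted p = 0.763 with an estimated correlation). In all, 281 genes were higher and 191 lower of 13644 tested.

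Some clusters came unevenly from the donors. Visium donor 4 gave 5975 of the 8664 spots of cluster 13, which were 42.5% of that donor's kept spots and led with SLC17A6 and PTGER3. Cluster 13 belongs to the AQP4/SLC1A2 region, of which donor 4 held 6302 spots. Visium donor 8 gave 1587 and donor 7 gave 1041 of the 4105 spots of cluster 17, which led with DEFB1 and CHRNA2. Visium donor 7 gave 4488 of the 12833 spots of the unnamed cluster 8.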
